A study of Heterocephalus glaber and Mus musculus with 6 samples.

How the data were processed

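RNA was measured in epidermal keratinocytes, the main cells of the outer skin layer, from dorsal skin of naked mole-rats and FVB mice, with 3 libraries per species. Per the labels' protocols, the epidermis was separated with dispase, dissociated to single cells and sorted for CD49f (integrin alpha-6), a surface protein of basal keratinocytes that endothelial cells also carry. Ribosomal RNA was depleted and strand-specific libraries were made. The labels give an age of 6 to 7 months for the naked mole-rats and 7 to 8 weeks for the mice, and name a different sequencing provider for each species. Species, age, provider, genome and gene annotation therefore go together and no test here can separate them. Nothing in the labels says whether the 3 libraries of a species came from separate animals, so p-values measure only the spread between these samples, which may be technical in part. Y-linked genes set mouse library 1 apart from libraries 2 and 3, so the mouse libraries were not all made from the same animals.

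The authors deposited 1 table per library with a whole-number count for each annotated gene or assembled locus, described as raw counts per the labels. The submitters' processing notes name cutadapt, FastQC, Bowtie2 and TopHat2, and list mm10 as the genome build for both species. The counting program, its settings and the genome used for the naked mole-rat reads are not given in the sources used here. In every library fewer entries held a count of 1 than a count of 3 (288 against 434 in naked mole-rat library 1, 641 against 781 in mouse library 1), so the values may be whole numbers derived from an estimated coverage. Each naked mole-rat table has 32784 entries, 21195 with an Ensembl gene identifier and 11589 for loci with the prefix MSTRG, which transcript assembly gives to merged loci. Each mouse table has 54364 entries, 42675 with an Ensembl identifier and 11689 assembled loci. Counts in Ensembl entries made up 9.34% ± 0.058 (SD, n = 3) of a naked mole-rat library and 11.2% ± 0.49 (SD, n = 3) of a mouse library.

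A comparison of single genes between the species had been fixed before the data were examined, as an edgeR quasi-likelihood test on genes matched by symbol, with camera tests of gene lists. Neither could be run. The tables share 0 Ensembl identifiers, 0 of the naked mole-rat identifiers are paired with a name in the reference tables used here, and assembled loci carry no names. There are 11589 MSTRG labels that occur for both species, but the numbering is separate in each: Spearman's rho of the mean counts over those labels, across loci, was −0.0071. No gene was therefore matched, and no name was assigned from an identifier or from its place in a table. The planned shares of keratin, ribosomal protein and mitochondrially encoded genes were also not computed, for the same reason.

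Mouse identifiers were joined to symbols, positions, lengths and GC content from GENCODE vM21 (GRCm38, the mm10 assembly). Of the 42675 mouse Ensembl identifiers, 42457 had a symbol and 42321 a symbol of their own. A named gene counted as measured at a mean of at least 10 counts over the 3 mouse libraries, which left 9965 genes. CPM, the count per 1000000 counts, was computed over all counts of a library, and log2 values with 0.5 added to each count. A library's deviation is its log2 CPM minus the mean of the other 2 mouse libraries. For each of the 25 gene lists, out of 31 fixed before the data were examined, that had at least 3 measured genes, the median deviation was set against 10000 random lists of the same size, matched on mean expression in 20 bins. The percentile describes these libraries and is not a test between conditions. Of the planned rule for genes the text names, 14 genes were to be named in any case, and the parts that rest on a test between species could not be applied. In their place, the genes named below are the 10 highest named mouse genes, members of the fixed lists, 3 Y-linked genes, the measured gene of a list added later, 2 naked mole-rat identifiers and mouse genes far apart between libraries. Apart from the 10 highest, the 14 fixed in advance and the gene of the added list, they were picked as examples after their values were seen.

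Shares of counts were compared between species with exact two-sided permutation tests of 3 against 3 values, for which 20 splits give a smallest p of 0.1. The share of the 10 highest entries was planned; the other concentration measures, the spread between libraries and the comparisons of mouse libraries were chosen after the tables had been seen. The common biological coefficient of variation (BCV) of each species was estimated with edgeR 4.0.16 in R 4.3.3 on entries that pass its filterByExpr function, with trimmed-mean (TMM) factors. Deviations of at least 2-fold were counted over entries with a mean of at least 10 counts. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. On simulated counts with a BCV of 0.2, the estimate was 0.198 over 16539 naked mole-rat and 0.199 over 18518 mouse entries. The list method was tested on 20 simulated sets of the 9965 mouse genes in which 200 genes changed in library 3. Each simulated list had 20 genes. All 200 lists with a log2 change of −1 and all 200 with −0.5 fell below the random range, with mean medians of −0.98 and −0.48. Of 400 unchanged lists in each case, 25 and 18 lay outside the range. The simulated genes varied independently, so these counts do not give the rate for lists of related genes. Nor do they apply to shorter lists, whose random ranges can be wider (−0.51 to 0.27 for 3 basal genes in library 3).

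Library totals ran from 28899862 to 31142663 counts in naked mole-rats and from 52499080 to 53465434 in mice. A count of 0 allows up to 3 counts, or 0.056 CPM in mouse library 2. Intervals and floors cover counting error only. No pair of libraries was a duplicate: the chi-square per degree of freedom between libraries of a species was at least 25.1. Alternatives comprised leaving out each library, leaving out the highest entries, thinning to the smallest library, other filters and scaling factors, and a fit on GC content and length.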

Results

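Keratinocytes sorted for CD49f were profiled in 3 naked mole-rat and 3 mouse libraries. Library totals were 28899862, 28969311 and 31142663 counts in naked mole-rats and 52499080, 53465434 and 52970733 counts in mice. The design asks how the keratinocytes of the 2 species differ. No gene could be matched between the tables, so the species are compared below by how their counts were distributed and by how far libraries of 1 species differed. Named genes are described for the mouse.

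Mouse keratinocyte libraries held more of their counts in the highest loci than naked mole-rat libraries did, largely through the single highest locus. The single highest locus took 10.2% ± 0.647 (SD, n = 3) of the counts in mice and 5.02% ± 0.882 (SD, n = 3) in naked mole-rats. The 10 highest loci together took 22.4% ± 0.77 (SD, n = 3) against 17.5% ± 1.73 (SD, n = 3), and the 100 highest 38.0% ± 0.891 against 32.6% ± 1.80. The highest loci that together held 50% of all counts numbered 386 ± 31.2 in mice and 518 ± 58.8 in naked mole-rats. All of the 10 highest loci in each species were assembled loci without a gene name, and the same locus was the highest in all 3 libraries of a species. Each of these comparisons separated the species without overlap and gave an exact two-sided permutation p of 0.1, the smallest that 3 against 3 libraries allow. With the highest locus of each species left out, the species overlapped in the share of the 10 highest, which differed by −0.48 percentage points (naked mole-rat minus mouse, exact permutation p = 0.6), and in the number of loci holding 50% of the counts, which differed by 25.3 (exact permutation p = 0.6). The share of the 100 highest still differed, by −1.91 points (exact permutation p = 0.1). The share of the next locus was then higher in naked mole-rats, by 0.861 points.

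**Figure D1:**
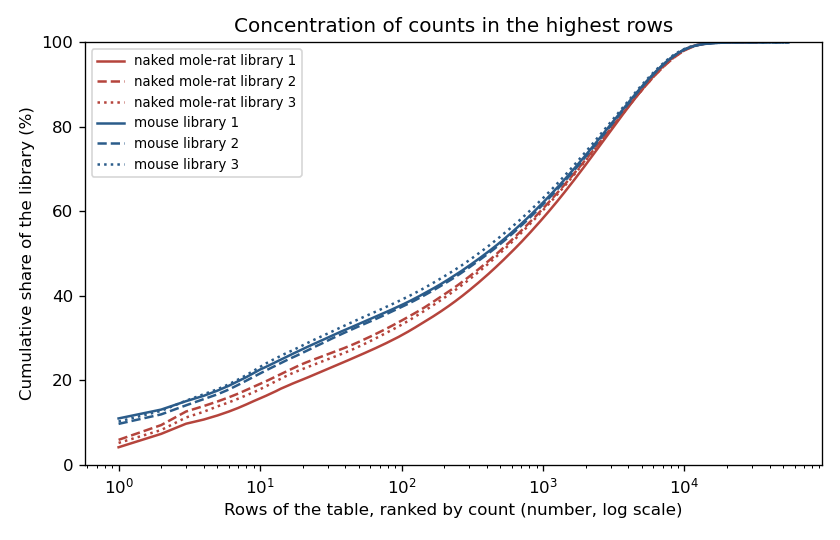
Cumulative share of each library's counts (percent, vertical axis) over table entries ranked from the highest count down (number, logarithmic horizontal axis), with 1 line per library. Mouse lines start at 9.63 to 10.9% for the first entry and naked mole-rat lines at 4.10 to 5.85%.

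The 3 naked mole-rat libraries differed from one another more than the 3 mouse libraries did, and this rested on naked mole-rat library 1. The common BCV from edgeR, the spread of a locus between libraries beyond counting error, was 0.280 in naked mole-rats and 0.165 in mice, a ratio of 1.70. The ratio lay between 1.67 and 1.91 over the other filters, scaling factors, depths and classes of loci that were tried. Without library 1 the BCV of the other 2 was 0.151, inside the range of mouse pairs, 0.139 to 0.1996. It was below the 0.165 of the 3 mouse libraries, but above their 0.146 when thinned to the smallest library. In library 1, 2683 of 17249 loci (15.6%) lay at least 2-fold from the mean of the other 2, against 1519 and 1483 in libraries 2 and 3. Spearman's rho across loci was 0.961 and 0.960 between library 1 and the others, and 0.987 between libraries 2 and 3. Among Ensembl entries with a mean of at least 100 counts, ENSHGLG00000000834 had 14.8 CPM in library 1 and 0 in the other 2, and ENSHGLG00000013983 had 0 CPM in library 1 and 6.42 and 6.97 in the other 2. These identifiers are not paired with gene names here.

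By CPM the highest named gene in mouse keratinocytes was Taok1, a protein kinase, with 217 ± 18.0 CPM (SD, n = 3). CPM is not corrected for gene length. Syne1, which encodes a nuclear envelope spectrin-repeat protein, had 215 ± 11.6 CPM, followed by Herc2, a ubiquitin ligase, at 204 ± 17.8 CPM, and Srgap2 at 202 ± 17.5 CPM. The rest of the first 10 were 4932438A13Rik, Hectd4, Mga, Setd2, Kcnq1ot1 and Bptf, from 194 down to 159 CPM. Taok1 lies on chromosome 11 from 77529162 to 77607815 (GRCm38). These values describe entries under a gene's own Ensembl identifier, most of them low in coverage. Over the protein-coding ones the 99th percentile was 9.71 CPM per kilobase of exon and the highest value 24.0, where all counts spread evenly over protein-coding exons would give 10.3. Taok1 had 17.5 and Syne1 5.32 CPM per kilobase, so Taok1 was not the highest by that measure. Of 22028 annotated protein-coding genes, 14605 (66.3%) had such an entry.

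Genes used by every cell were rarely among these entries, and the keratinocyte lists varied. Of the fixed lists, 0 of 49 ribosomal proteins, 0 of 38 proteasome genes and 0 of 46 nuclear oxidative phosphorylation genes had one, and 3 of 21 basal keratinocyte, 2 of 25 suprabasal, 7 of 34 cornified envelope, 8 of 28 barrier lipid and 13 of 19 wound genes did. Of the 14 genes chosen in advance, Cdkn2a, a cell cycle inhibitor, had counts of 0, 5 and 0 in mouse libraries 1, 2 and 3, and Has2, a hyaluronan synthase, had 0, 18 and 3. The other 12, among them Itga6, Krt5, Krt14 and Trp63, were not analysed here, so those markers give no check of the identity of the sorted cells. The basal genes that were measured were Itga2, an integrin subunit, at 48.3 ± 5.58 CPM, Ass1 at 8.57 ± 2.78 CPM and Syt8 at 0.851 ± 0.339 CPM (SD, n = 3 each). Of the suprabasal and cornified lists, Dsc2, a desmosomal cadherin, had 7.61 ± 0.993 CPM, the keratin gene Krt2 2.60 ± 0.578 CPM and the transglutaminase gene Tgm3 14.3 ± 3.97 CPM. Gapdh, a glycolytic enzyme of every cell, had 16.5 ± 1.61 CPM. A low value or a 0 is a value of that entry only, and says nothing of reads assigned to assembled loci.

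Most markers of other skin cell types that had an entry of their own were low in the mouse libraries. The endothelial gene Pecam1 had 10, 14 and 11 counts, and Kdr, Cdh5 and Emcn had 0 in each library. Among melanocyte genes Dct had 15, 13 and 17 counts and Tyr had 0, while Mitf, which other cells also express, had 8.95 ± 1.13 CPM. The Merkel cell genes Atoh1, Sox2, Krt8, Krt18 and Krt20 had 0 counts. Ptprc, a marker of all leukocytes, had 24, 41 and 48 counts, and the T cell gene Cd3g 6, 29 and 37. Among fibroblast genes Dcn had 26, 31 and 29 counts and Pdgfrb 0, but Col6a3, a collagen VI chain, had 55.2 ± 6.67 CPM and Fn1, fibronectin, 11.0 ± 4.63 CPM (SD, n = 3). Blood and muscle were represented by Alas2 at 1.68 ± 0.506 CPM, and the sebaceous gland by Awat2 at 0.403 ± 0.117 CPM. Of 127 annotated genes in these 8 lists, 95 had an entry and 35 were measured. Genes without an entry could not be read, and they may be the more abundant ones. Low counts here therefore do not show how pure the sorted cells were.

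Within the mouse group, genes of mitosis were lower in library 3 than in the other 2. The median deviation of the 30 measured genes was −1.11 on the log2 scale, or 0.462 times the mean of the others, and all 30 were lower in library 3 than in both other libraries. Cenpf, a kinetochore protein, had 34.4, 26.8 and 9.76 CPM in libraries 1, 2 and 3, Kif23, a cytokinesis motor, 34.0, 29.9 and 13.4, Ccnb1, cyclin B1, 14.4, 9.50 and 4.85, and Foxm1, a transcription factor of mitotic genes, 12.9, 12.4 and 5.72. The median lay below all 10000 matched random lists, whose central 95% ran from −0.20 to 0.03. In libraries 1 and 2 the median was 0.66 and 0.45, above the range in both, but each is set against a mean that includes library 3: without it the medians were 0.13 and −0.13, still outside the random ranges (−0.15 to 0.067 and −0.067 to 0.15). Genes of S phase and DNA replication differed less: the median of 15 genes was −0.26 in library 3, where 15 of 15 were lower than in both others, and 0.23 in library 2. Pole, a replicative polymerase subunit, had 56.0, 55.8 and 39.0 CPM and Pola1 46.9, 54.5 and 39.5. Without library 2 the S phase median of library 3 was −0.18, inside the random range.

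**Figure D2:**
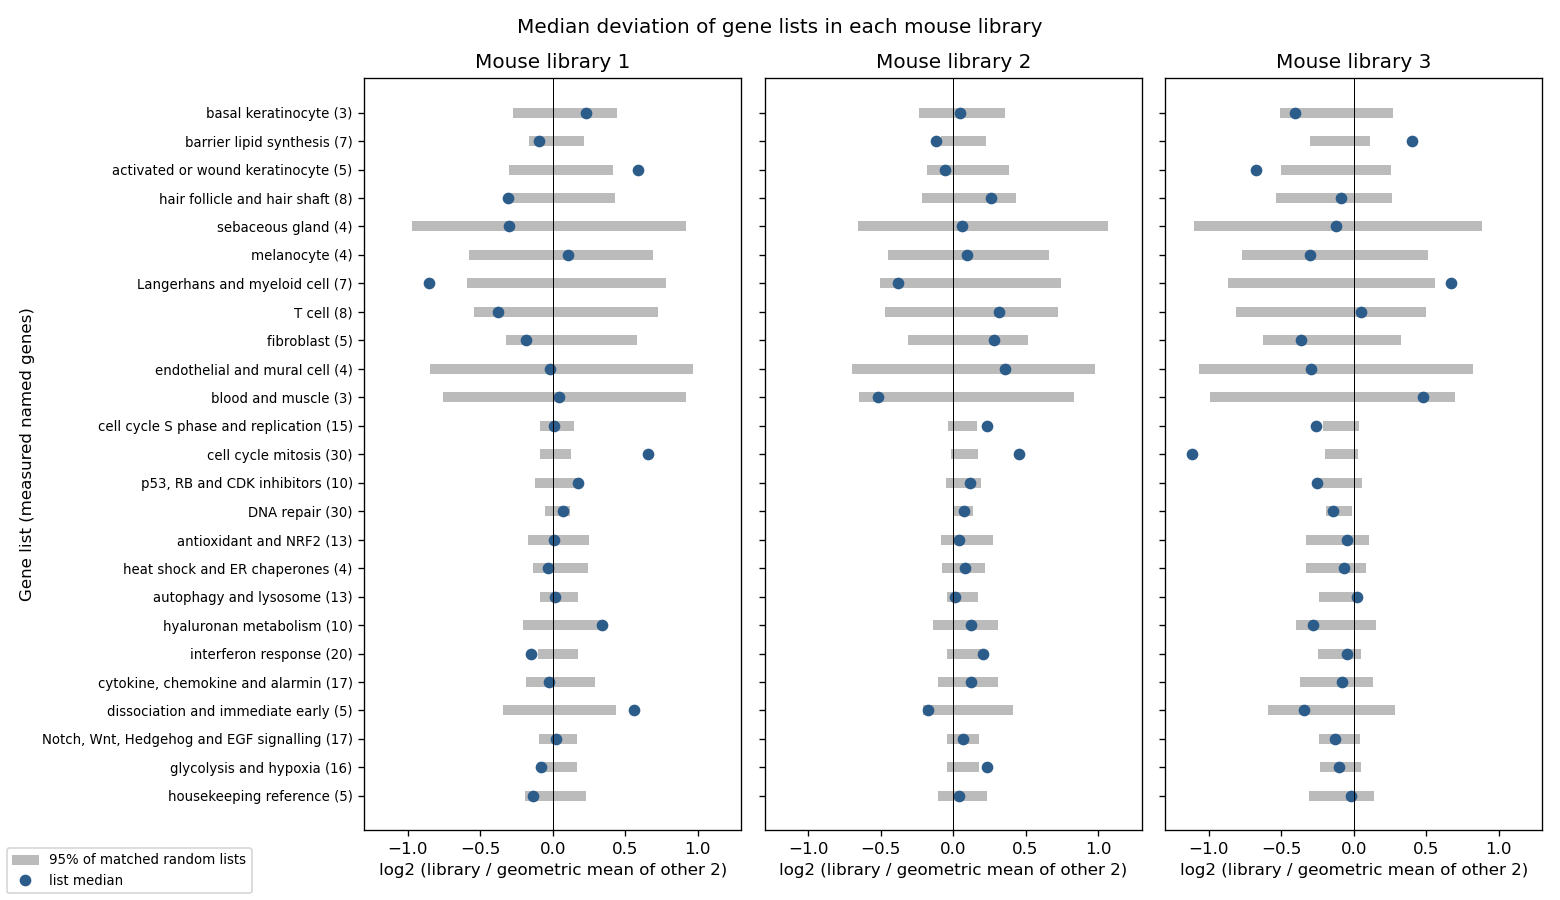
Median log2 deviation of each gene list (points, horizontal axis) in mouse libraries 1, 2 and 3 (panels), with the central 95% of matched random lists (grey bars) and the number of measured genes in parentheses. Mitosis genes sit at −1.11 in library 3 and at 0.66 and 0.45 in libraries 1 and 2.

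Genes of barrier lipid synthesis were higher in the same mouse library 3. Their median deviation was 0.40, above the range of matched random lists (−0.30 to 0.11), and 5 of 7 genes were higher there than in both other libraries. In library 2 the median of these genes was −0.12, below its random range (−0.084 to 0.22). Without library 3 that median reversed to 0.0020, inside the range. Sdr9c7, which acts on lipids of the skin barrier, had 9.60, 13.5 and 21.4 CPM in libraries 1, 2 and 3, the epidermal lipase gene Lipk 1.43, 1.74 and 3.68, and Ugcg, glucosylceramide synthase, 26.3, 30.0 and 40.6. Sptlc2, a subunit of serine palmitoyltransferase, had 39.4, 39.4 and 39.3 CPM. Of the measured basal, suprabasal and cornified genes, all but Dsc2 were lower in library 3 than the mean of the others. All 3 measured basal genes were lower there than in both others, with deviations of −0.27 for Itga2, −0.40 for Ass1 and −0.63 for Syt8, and their median of −0.40 lay inside the random range (−0.51 to 0.27). Dsc2 had a deviation of 0.31, Krt2 −0.10 and Tgm3 −0.43.

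**Figure D3:**
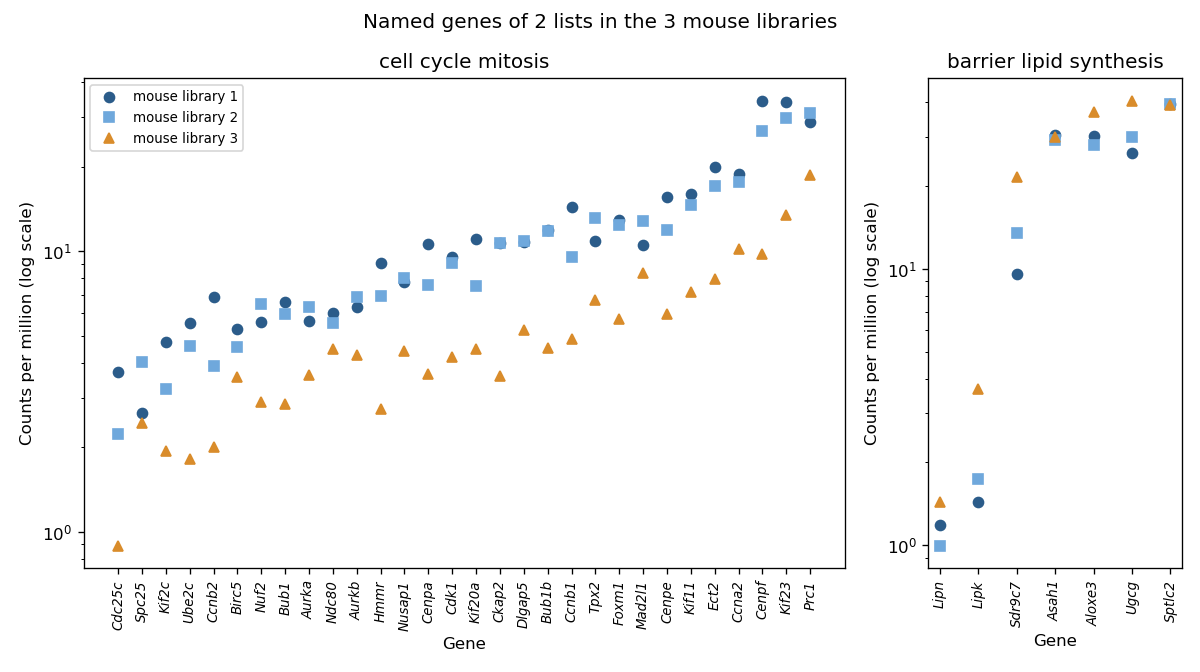
CPM (logarithmic vertical axis) of each measured gene of the mitosis and barrier lipid lists (horizontal axis) in mouse libraries 1, 2 and 3 (circles, squares and triangles). Library 3 is the lowest for all 30 mitosis genes and the highest for 5 of 7 barrier lipid genes.

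Several smaller gene groups also differed between the mouse libraries, of which library 1 alone had high counts of Y-linked genes (Ddx3y 3483, 0 and 0). The immediate early list, genes induced quickly by tissue dissociation among other stimuli, had a median of 0.56 in library 1, with 4 of 5 genes highest there. Only these 5 of its 29 genes had an entry, and Dusp2 was lowest in library 1, with 12, 40 and 22 counts. Nr4a3 had 4.04, 1.76 and 2.10 CPM and Klf2 11.9, 9.69 and 6.70. The wound list had 0.59 in library 1 and −0.68 in library 3, but its 5 genes went both ways: Hbegf had 32.3, 24.8 and 17.7 CPM and Areg, another EGF receptor ligand, 6.65, 6.96 and 9.51. Without library 3 the wound median of library 1 was −0.066, and without library 1 that of library 3 was −0.47, both inside the random range. Interferon response genes had −0.15 in library 1 and 0.20 in library 2, outside the random range in 4 of 5 and in 1 of 5 alternatives. Irf9, a transcription factor of the interferon response, had 36.4, 49.0 and 53.6 CPM. Glycolysis and hypoxia genes had 0.23 in library 2, but without library 1 their median of 0.21 lay inside the random range. In library 2, Pfkfb3 had 48.0 CPM against 26.4 and 36.3, and Vegfa 23.2 against 14.9 and 17.0.

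Langerhans and myeloid genes had a median of −0.85 in mouse library 1 and 0.67 in library 3, most of them on few counts. Of the 7 measured genes, 4 were higher in library 3 than in both others. Lyz2, lysozyme, had 0, 0 and 59 counts. Cd83, the highest of the 7, went the other way with 179, 293 and 125 counts, and Aif1 had 23, 8 and 9. With protein-coding genes alone as the random pool neither median lay outside the range, nor did that of library 1 without library 3 (−0.68) or that of library 3 without library 1 (0.24). Hair follicle genes had −0.31 in library 1, outside the range in 2 of 5 alternatives, and Foxn1, a transcription factor of hair and epidermal differentiation, had 28.4, 32.4 and 41.6 CPM. Over all lists 16 of 75 medians lay outside the central 95% of random lists, where 3.75 would for lists of unrelated genes. Genes of 1 list may vary together and its 3 values are not independent, so 3.75 is not the number to expect outside that range. The other 16 lists lay inside it in every library, with medians from −0.52 to 0.48: basal keratinocyte, sebaceous, melanocyte, T cell, fibroblast, endothelial, blood and muscle, p53 and CDK inhibitors, DNA repair, antioxidant, heat shock, autophagy, hyaluronan, cytokine, Notch and Wnt signalling, and housekeeping genes. Random ranges of short lists were wide, such as −0.65 to 0.84 for the 3 blood and muscle genes in library 2. A median inside the range therefore does not show that a list was unchanged. A further 6 lists had too few measured genes to be scored.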

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

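Y-linked genes were high in mouse library 1 and at or near 0 in libraries 2 and 3. They are in none of the fixed lists, and entered the mouse totals and BCV like other entries. Ddx3y, an RNA helicase gene (chromosome Y, 1260771 to 1286629, GRCm38), had 3483, 0 and 0 counts in libraries 1, 2 and 3. In library 1 that is 66.3 CPM, at least 1171-fold higher than 3 counts in either of the others allow. Uty, a histone demethylase gene, had 3185, 0 and 0 counts, or 60.7 CPM in library 1, at least 1071-fold higher. Kdm5d had 2625, 3 and 0 counts, or 50.0009 CPM in library 1, a ratio of 891 to library 2 with an exact 95% counting interval of 305 to 4324. The labels give no sex for any library, and the mouse group is treated as 1 group throughout.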

How the results depend on the processing

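Of 145 alternative values for 23 results, 58 of 78 list medians kept their direction and their side of the random range, and 19 of 22 BCV values moved by at most the SD of that species' 3 leave-one-out values, 0.101 in naked mole-rats and 0.0314 in mice. For the 5 shares of counts no p could pass a threshold, so values were judged by direction and by a rule set after they had been seen, a move of at most 1 pooled SD: 44 of 45 kept the direction and 40 of these moved by no more than that. The other 5 all came from leaving out the highest locus. The share of the single highest then reversed to 0.861 points, that of the 10 highest was −0.48 points (exact permutation p = 0.6), of the 100 highest −1.91 and of Ensembl entries −2.63, and the loci holding 50% differed by 25.3 (exact permutation p = 0.6). Leaving out each library was planned for the share of the 10 highest entries, and all other alternatives were chosen after seeing the data. With the replicate number as a block, the share of the single highest differed by −5.23 points (exact sign-flip p = 0.25, the smallest that 3 pairs allow). No matched gene could show whether the numbers pair the libraries. The block leaves each difference unchanged by arithmetic, and thinning is not expected to change a share. Neither could therefore have moved the 5 shares far, and neither lends them support. Without a filter the BCV was 0.207 in mice and 0.369 in naked mole-rats. Leaving out a library gave 0.139 to 0.1996 in mice and 0.151 to 0.328 in naked mole-rats. The naked mole-rat SD of 0.101 is wide because it includes the 0.151 without library 1, so the unfiltered 0.369 against 0.280 counted as within it. The mitosis and barrier lipid medians of mouse library 3 stayed outside the random range in each alternative, from −1.19 to −0.94 and from 0.29 to 0.56. With a minimum of 50 counts the wound medians were 0.19 in library 1 and −0.21 in library 3, and the interferon median of library 2 was 0.16, all inside the range. With protein-coding genes as the pool the same held for hair follicle genes (−0.31), myeloid genes (−0.85 and 0.67) and interferon genes in library 2 (0.19), and after the GC and length fit for hair follicle (−0.33) and interferon genes in library 2 (0.080). Leaving out a mouse library gave ranges of −0.43 to 0.0020 for barrier lipids and −0.13 to 1.01 for mitosis in library 2, 0.13 to 1.19 for mitosis in library 1, 0.16 to 0.34 for S phase in library 2, −0.066 to 0.87 and −0.87 to −0.47 for the wound list in libraries 1 and 3, −0.47 to −0.30 for hair follicle, −1.26 to −0.68 and 0.24 to 1.26 for myeloid genes, −0.34 to −0.18 for S phase in library 3, −0.30 to −0.082 and 0.17 to 0.30 for interferon in libraries 1 and 2, and 0.21 to 0.26 for glycolysis, whose lower end lay inside the random range. Fewer libraries compared is part of these changes by construction, and the cause of the others was not tested. The other ways of testing genes and lists between species that had been fixed in advance (DESeq2, voom, other scalings, filters and length offsets, fry) and 2 other denominators for shares were not run, since no gene was matched. Most myeloid genes rest on few counts, and lists were not thinned, so the effect of depth on them is not known.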

Other observations

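Genes outside the fixed lists, chosen after their values were seen, also differed between the mouse libraries. Itgb8, an integrin subunit, had 8.90, 9.50 and 1.87 CPM in libraries 1, 2 and 3, Adgrl3, an adhesion receptor, 15.0, 12.5 and 3.83, and Enpp1, an ectonucleotidase, 5.45, 4.75 and 1.23. Gpr37 had 3.75, 5.54 and 10.3 CPM. Library 1 was lowest for Pyy, a peptide hormone gene, at 0.610 CPM against 6.85 and 5.02, and highest for Rfx2, a transcription factor, at 74.3 against 27.3 and 19.8. Of the 9965 measured genes, 511, 482 and 353 were at least 2-fold higher in libraries 1, 2 and 3 than the mean of the others, and 416, 290 and 679 at least 2-fold lower. The median deviation over these genes was 0.047, 0.073 and −0.098.

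Except for the tests of a differentiated cell mix and of overlapping genes, the tests below were chosen after the result they bear on was seen. The low mitosis genes of mouse library 3 may reflect fewer dividing cells among those sorted. Bias from GC content and transcript length is argued against by the median after a fit on both, −0.94, below its random range. Dilution by other cells as the whole cause would lower keratinocyte genes alike. The median of the 18 measured genes of the 5 keratinocyte lists instead lay 1.11 above the mitosis median (95% bootstrap interval over genes 0.67 to 1.51). Of the 18, 17 lay above the mitosis median. The size of the gap rests in part on the 7 barrier lipid genes, already seen to be higher (median 0.40). A smaller dilution stays open, since 9 of the 18 were lower in library 3, the 3 basal genes among them (median −0.40). The myeloid median was higher there (0.67), with 4 of 7 genes higher than in both other libraries. A shift of the sorted cells toward differentiation also stays open: 1 of 18 differentiation genes outside the fixed lists was measured, Plb1, with a deviation of −5.00 on few counts, so that test decides nothing, and no biological explanation was tested with independent data.

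Abundant mouse transcripts are a candidate source of the loci without a gene name. Genes of the ribosomal, proteasome, oxidative phosphorylation and housekeeping lists had an entry of their own in 5 of 157 cases (3.18%), and markers of other cell types in 95 of 127 (74.8%), a difference of 71.6 percentage points (Fisher's exact test, p = 1.63e-40, over genes, which are not independent replicates). Such a pattern would follow if assembled loci had taken up expressed genes. It was seen before the test was chosen, so the p adds no further support. Merging of protein-coding genes that overlap on the same strand would account for few of them. Of the 7423 protein-coding genes without an entry, 89.7% overlap no other protein-coding gene on that strand, against 95.8% of those with an entry. Such overlap was thus more frequent in genes without an entry, and overlap with other types of genes was not counted.

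Naked mole-rat library 1 stood apart from libraries 2 and 3. Depth is an unlikely cause, because libraries 1 and 2 had nearly equal totals and yet a BCV 2.15 times that of libraries 2 and 3. A few loci taking most of the counts would rescale all others by 1 factor, and this is argued against: with the 10 highest left out and each library's median deviation removed, 15.7% of loci in library 1 still lay at least 2-fold from the mean of the others, 1.77 times the higher of the shares in libraries 2 and 3 (8.85% and 8.63%). RNA integrity, dissection and differences between animals were not tested, and no biological explanation was tested.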
